A study of Arabidopsis thaliana with 2 samples.

How the data were processed

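The data are 2 small RNA libraries of Arabidopsis thaliana seedlings, 1 per group, grouped by the source names in the labels. Per the labels' protocols, RNA of 15 to 30 nt was cut from a gel loaded with 500 µg of total RNA. Adapters were ligated to its 5′ end and then its 3′ end, and the reverse-transcribed and amplified product was sequenced on an early Illumina instrument. Plants grew with 16 h light and 8 h dark at 22 °C. The treated plants had 100 µM MeJA for 8, 16 and 24 h, and how these times and the ages of 3 to 5 weeks were combined in the library is not stated in the labels.

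The authors deposited raw read counts per distinct sequence, with the length and the sequence, per the file headers. The counts are whole numbers, not normalized, and sequences read once were kept (82.8% and 82.7% of the distinct sequences). The sequences run from 18 to 30 nt, so shorter RNA was not analysed here. How adapters were removed and whether the authors matched the reads to a genome, with which aligner and build, is not given in the sources used here.

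Every sequence was matched to the TAIR 10.1 assembly, both strands, with 0 mismatches allowed, by a hash lookup written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0. A read with several matches was divided equally among them, and 58.6% and 49.6% of matched reads had 1 match. Each match was given to the first class that applied in the order rRNA, tRNA, snRNA and snoRNA, miRNA, TAS, pseudogene, protein-coding, other RNA, intergenic, with organelle matches kept apart. The design placed transposons in this order, but transposon annotation was not used here and pseudogene took their place. The nuclear large-subunit rRNA lacks an annotation at the 2 rDNA loci, so 3700 bp downstream of the last annotated rRNA were counted as rRNA, a choice made after the annotation was seen. Matching was tested on simulated reads with known positions.

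miRNA families were sums of reads identical to the mature sequences of a list of 69 families and 98 mature miRNAs. That list was written before the data were examined, and its sequences were kept where they lie in an annotated miRNA gene. Gene lists and miRNA lists were written at the same time. The gene lists are jasmonate synthesis, jasmonate response, photosynthesis, small RNA machinery, seed storage, flower, root and defence. The miRNA lists group families by target function. Genes were counted as sense reads on exons, TAS loci as 21-nt reads on either strand, and 24-nt reads in windows of 1000 bp. Paralogs share divided reads, so single members of families such as RBCS, CAB and JAZ are uncertain.

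The main scaling is reads per 1000000 genome-matched reads (RPM). Each ratio has a 95% exact conditional binomial (Clopper-Pearson) interval, and each share a 95% Wilson interval. With 1 library per group no test across replicates exists. A family, locus, window or gene is called when it has 20 or more reads in the 2 libraries together, differs 2-fold or more and has an interval that excludes 1. Called means larger than counting error between these 2 libraries. A feature at 0 reads is given as a bound against a floor of 3 counts, which is 1.36 RPM in the library labelled MeJA and 1.73 in the library labelled aos. This bound takes the reads of the other library as exact, so the lower bound from the interval is given beside it. Log2 ratios used a pseudocount of 0.5 reads. The median of a list was set against 10000 random lists of the same size matched on level, as a description of these libraries.

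The text names features by a rule fixed before the data were examined. For miRNAs these are the 8 families with the largest called ratio in each direction among those with 100 or more reads, the 8 most abundant families, and miR319, miR393, miR395, miR398, miR399 and miR163. For the rest they are all 8 TAS loci, AOS and up to 4 members per gene list with the most reads, the 5 most abundant tRNA groups, the 4 windows with the largest called ratio in each direction among those with 100 or more reads, and the 5 most abundant sequences of each library. Other families named with a list or a scaling are members of that list and were named after their values were seen.

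The calling rule was tested on simulated counts drawn from the libraries' means. For the 44 miRNA families in 50 simulations, 94.4% of 3-fold and 99.6% of 6-fold changes were recovered and 0.661% of unchanged families were called. For the 16406 windows, 91% of 3-fold and 100% of 6-fold changes were recovered and 1.64% of unchanged windows were called. For the 1111 genes these values were 85%, 96% and 1.71%. These simulations hold counting error only, with no spread between plants or preparations, so they do not give the rate of false calls between 2 separate samples.

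Alternatives to the scaling were reads per 1000000 reads in the file, without structural RNA, edgeR's TMM (edgeR 4.0.16, R 4.3.3) and median of ratios, the last pair over the miRNA families. Others changed which reads count, the read minimum, the fold threshold, the window size, the treatment of several matches and the depth. Statistics used scipy 1.17.1 and figures matplotlib 3.10.9. Reads without a genome match were compared with 7 T-DNA and vector segments. Their sequences were written from general knowledge, not taken from a reference, after the unmatched reads had been looked at.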

Results

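Small RNAs of Arabidopsis thaliana (Col-0 background) were sequenced from seedlings of 3 to 5 weeks in 2 libraries, 1 per group. The first library is labelled wild type treated with 100 µM methyl jasmonate (MeJA, the volatile ester of the wound hormone jasmonic acid) for 8, 16 and 24 h. The other is labelled untreated aos, a mutant of allene oxide synthase, the enzyme that makes the first committed intermediate of jasmonate. By the labels, the comparison sets a plant with much jasmonate against a plant that cannot make it, and asks which small RNAs differ. The library labelled MeJA held 2802264 reads of 1446185 distinct sequences, and the library labelled aos held 2172676 reads of 1024355 distinct sequences. Of these reads 79.0% and 80.04% matched the genome perfectly, which gave 2213803 and 1739030 matched reads. There were no replicates, so every difference compares these 2 libraries and not the conditions. The 95% intervals and the floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. All ratios are reads per 1000000 genome-matched reads (RPM) in the library labelled MeJA over the library labelled aos.

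The gene that the mutant lacks was examined first, and its reads went against the labels. AOS (AT5G42650, chromosome 5, 17097564 to 17099595, minus strand) had 0 sense reads on its exons in the library labelled MeJA and 7 in the library labelled aos. Against the floor of 3 counts, AOS was at least 2.97-fold higher in the library labelled aos. The 95% upper bound of the ratio was 0.545, so counting error in its own reads allows a difference as small as 1.83-fold. Its 7 reads are under the minimum of 20 for a call. Genes that jasmonate is known to induce went the same way. Their 17 members together had 5 sense reads in the library labelled MeJA and 81 in the library labelled aos, a ratio of 0.0485 (0.0153 to 0.118), and 17 of 17 had more reads in the library labelled aos. Of the protein-coding genes outside the jasmonate lists, 8611 were also higher in RPM in the library labelled aos and 4721 in the library labelled MeJA.

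In the jasmonate response list, VSP2 (AT5G24770, chromosome 5, 8500468 to 8502224), a vegetative storage protein and a classic jasmonate marker, had 0 and 21 reads. Against the floor it was at least 8.91-fold higher in the library labelled aos (6.63-fold by the interval), and it was the only member with 20 or more reads. VSP1 (AT5G24780) had 0 and 14 reads (8.34 RPM in the library labelled aos before its divided reads were rounded), at least 6.15-fold higher in the library labelled aos against the floor (4.22-fold by the interval). ST2A, a jasmonate-inactivating sulfotransferase, had 1 and 6, and MYC2, the main transcription factor of the response, had 3 and 6, with an interval of its ratio that reached 1.84. Without VSP1 and VSP2, the other 15 members had 5 and 46 reads, a ratio of 0.0854 (0.0265 to 0.214). The jasmonate synthesis genes other than AOS had 35 and 56 reads, a ratio of 0.491 (0.312 to 0.762). Among them LOX2 (AT3G45140, chromosome 3, 16525245 to 16529352), the plastid lipoxygenase, had 32 and 29 reads, a ratio of 0.867 (0.509 to 1.49). LOX3 had 0 and 9 and OPR3 had 2 and 5. With AOS included, the synthesis list had 35 and 63 reads, a ratio of 0.436 (0.280 to 0.670). LOX2 also had 20 and 12 antisense reads. Among reads shorter than 20 nt or of 25 nt and more, the synthesis genes other than AOS had 3 and 22. Most LOX2 sense reads in the library labelled MeJA therefore had other lengths. The near-equal LOX2 counts do not compare fragments of those shorter and longer lengths.

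Photosynthesis genes had 160 and 132 reads, a ratio of 0.952 (0.751 to 1.21). The median log2 ratio of the 5 members with 20 or more reads was -0.35, at percentile 13.0 of 10000 random lists matched on level, and RCA, the Rubisco activase, had 27 and 19 reads, LHCB2.1 15 and 10, LHCA3 9 and 12, and PSBO1 12 and 13. Small RNA machinery genes had 36 and 24 reads, a ratio of 1.18 (0.684 to 2.06), with AGO1, the main slicer protein, at 18 and 9 and DCL1, the miRNA-processing enzyme, at 10 and 7. Seed storage genes had 1 and 2 reads, flower genes 0 and 1, and root genes 3 and 3. Defence genes had 2 and 10 reads, a ratio of 0.157 (0.0167 to 0.737), of which PR3 and PR4, chitinase-related genes, had 0 and 5 and 2 and 4. PDF1.2A had 0 and 1, and the other members, PR1, PR2 and PR5 among them, had none, so the ratio does not describe defence genes at large. All protein-coding genes outside the 2 jasmonate lists together had 80281 and 69652 reads, a ratio of 0.905 (0.896 to 0.915). Among reads shorter than 20 nt or of 25 nt and more, they had 3819 and 10116, a ratio of 0.297 (0.286 to 0.308). Over those lengths the jasmonate response list had 1 and 50, a ratio of 0.0157 (0.00039 to 0.0916). Over all genes, 62 of the 1111 with 20 or more sense reads were called higher in the library labelled MeJA and 77 lower. Without structural RNA in the scaling these counts were 35 and 96. Fragments of an mRNA in a small RNA library are a weak check of a genotype, and an aos allele could still make RNA. Among reads shorter than 20 nt or of 25 nt and more, AOS had 0 and 4 reads (upper bound 1.19). More mRNA fragments of every gene could therefore account for AOS alone. Because of the jasmonate response list, with AOS in the same direction, both libraries are named below by their labels and no direction is read as an effect of MeJA.

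**Figure D1:**
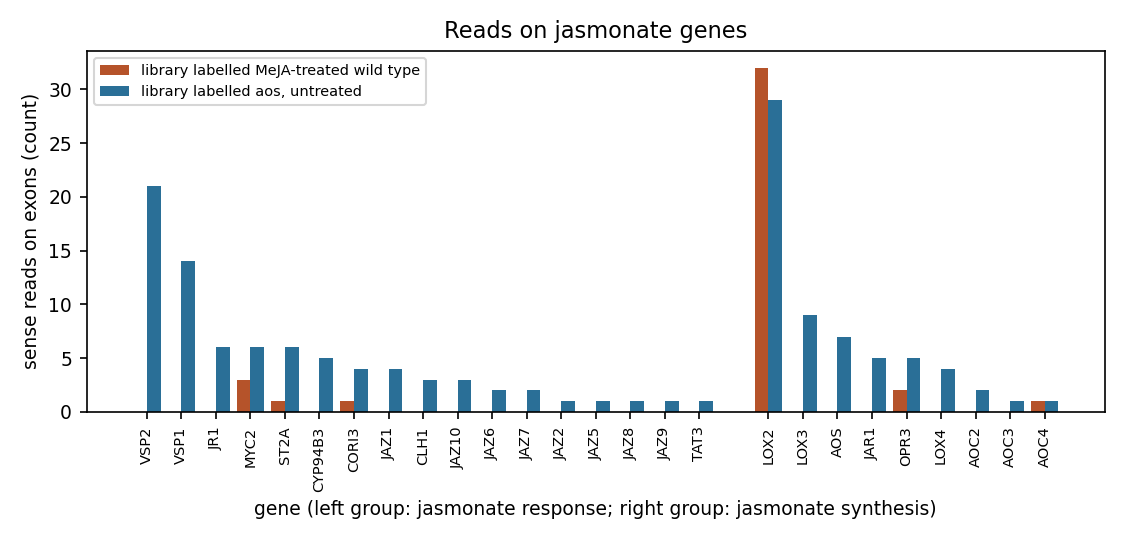
Sense reads on exons (vertical axis, counts) of each jasmonate response gene (left group) and jasmonate synthesis gene (right group) with at least 1 read, 1 bar per library and no error bars since there was 1 library per group. The library labelled aos has 21 reads on VSP2, 14 on VSP1 and 7 on AOS where the library labelled MeJA has 0. LOX2 is near equal at 32 and 29 reads of all lengths. Among reads shorter than 20 nt or of 25 nt and more, the synthesis genes other than AOS had 3 and 22.

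The length profile showed the peaks at 21 nt (miRNAs and trans-acting siRNAs) and 24 nt (heterochromatic siRNAs) that plant small RNAs have. Reads of 24 nt made up 42.5% (95% Wilson interval 42.4 to 42.5) of the library labelled MeJA and 38.2% (38.1 to 38.2) of the library labelled aos, and reads of 21 nt made up 17.3% and 16.7%. Reads of 23 nt were also many, at 20.6% and 16.7%. The 24-nt to 21-nt ratio was 2.45 (2.45 to 2.46) in the library labelled MeJA and 2.28 (2.27 to 2.29) in the library labelled aos, against whose label the jasmonate response and AOS reads ran, a ratio of ratios of 1.08. This order turned around, to 0.903, when distinct sequences were counted in place of reads. Reads of 25 to 30 nt were the clearest difference, with 3.79% (3.77 to 3.81) against 11.5% (11.4 to 11.5).

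**Figure D2:**
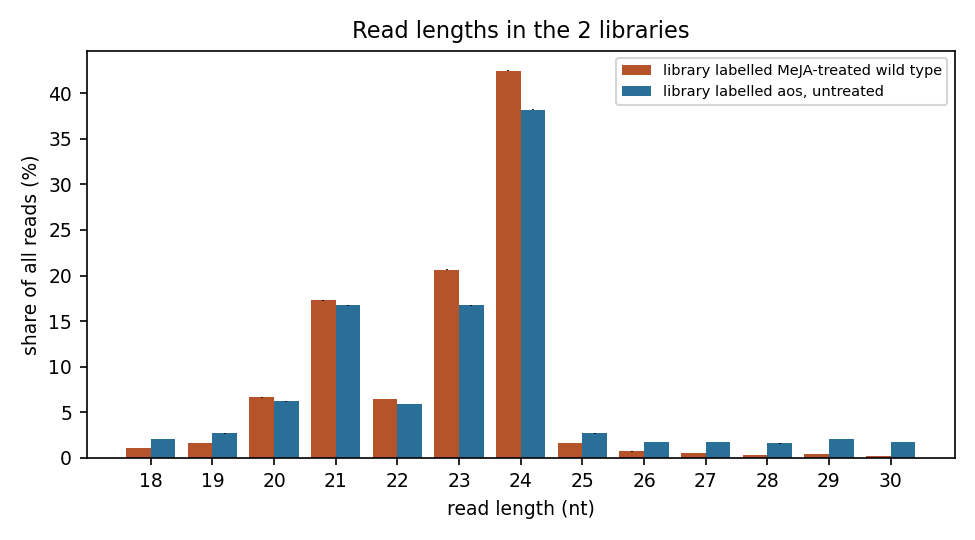
Share of all reads (vertical axis, %) at each read length from 18 to 30 nt (horizontal axis), 1 bar per library, with 95% Wilson intervals that are narrower than the bar edges. The library labelled aos has 38.2% of its reads at 24 nt against 42.5%, and 11.5% against 3.79% at 25 to 30 nt.

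Fragments of structural RNA set the libraries apart. Nuclear and organelle rRNA, tRNA, snRNA and snoRNA made up 5.60% of matched reads in the library labelled MeJA and 18.1% in the library labelled aos, 3.23-fold more in the latter. By class, nuclear rRNA had 4.33% and 12.9% (ratio 0.337, 0.334 to 0.339) and nuclear tRNA 0.849% and 3.55% (0.240, 0.236 to 0.243). Nuclear snRNA with snoRNA had 0.0400% and 0.177% (0.226, 0.209 to 0.244). Reads of the mitochondrial genome (0.206% and 0.440%) and the plastid genome (1.98% and 3.57%) include the organelle rRNA and tRNA of the total above. They were also lower in the library labelled MeJA, with ratios of 0.469 (0.452 to 0.487) and 0.554 (0.547 to 0.561). The jasmonate response and AOS reads ran against the labels behind these directions.

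The tRNA fragments came mostly from a few isoacceptors. Those of glycine (anticodon TCC) had 6027 and 19492 reads, a ratio of 0.243 (0.236 to 0.25), and those of aspartate (GTC) 2334 and 11685, a ratio of 0.157 (0.150 to 0.164). Proline (TGG) had a ratio of 0.267 (0.252 to 0.282) and alanine (AGC) of 0.554 (0.527 to 0.582). Histidine (GTG) had 295 and 4165 reads, a ratio of 0.0556 (0.0493 to 0.0626). Reads that began at the 5′ end of the tRNA were 76.8% (76.1 to 77.4) of tRNA reads in the library labelled MeJA and 60.7% (60.3 to 61.0) in the library labelled aos.

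The regulatory classes were close to each other. Intergenic reads, the largest class in both libraries, were 53.6% and 44.3% of matched reads (ratio 1.21, 1.207 to 1.214), reads in miRNA genes 17.4% and 16.0% (1.09, 1.08 to 1.09), and TAS genes 3.28% and 2.68% (1.22, 1.21 to 1.24). Pseudogenes had 8.06% and 6.63% (1.22), the antisense strand of protein-coding genes 4.10% and 3.50% (1.17), their sense strand 4.98% and 5.12% (0.973), and other annotated RNA 1.13% and 1.16% (0.972). None of these classes reached 2-fold. Structural RNA is part of the total behind every RPM, and with it left out of the scaling the ratios were 1.05 for intergenic, 0.943 for miRNA, 1.06 for TAS, 1.06 for pseudogene, 1.01 for antisense and 0.844 for sense reads. This scaling moved every log2 ratio by -0.20, edgeR's TMM over the miRNA families by -0.42, and median of ratios over them by -0.26, so ratios this close to 1 carry no direction here.

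**Figure D3:**
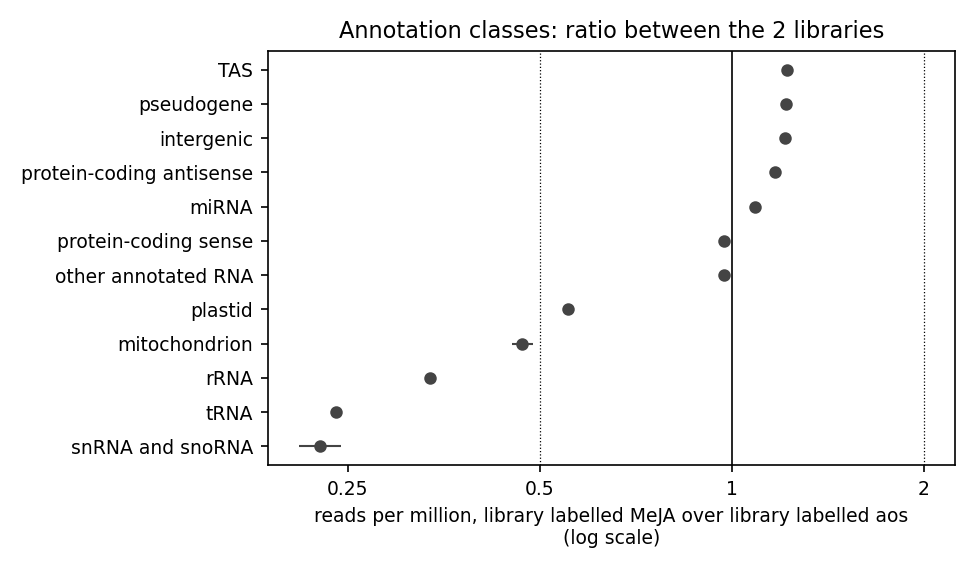
Ratio of RPM, library labelled MeJA over library labelled aos (horizontal axis, log scale), for each annotation class, with 95% counting intervals that are mostly narrower than the points; the dotted lines mark 2-fold. Nuclear rRNA (0.337), tRNA (0.240) and snRNA with snoRNA (0.226) are more than 2-fold lower, while miRNA reads lie at 1.09 and at 0.943 when structural RNA is left out of the scaling.

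Of 69 miRNA families listed, 62 had a read and 44 had 20 or more, of which 5 were called higher in the library labelled MeJA, 1 was called lower and 38 were not called. Of the 44, 19 had an interval above 1, 10 had one below 1 and 15 lay within counting error. With edgeR's TMM the counts were 4 higher and 6 lower, and without structural RNA 5 and 3. The jasmonate response and AOS reads ran against these labels. Among families with 100 or more reads, miR857, which targets a copper-containing laccase, was highest with 237 and 40 reads, a ratio of 4.65 (3.32 to 6.68). Its sequence UUUUGUAUGUUGAAGGUGUAU lies on chromosome 4 at 7878198 to 7878218, minus strand, in MIR857 (AT4G13554). miR846 had 153 and 39 reads, a ratio of 3.08 (2.16 to 4.50), and miR394, which acts on an F-box gene of leaf development, had 145 and 45, a ratio of 2.53 (1.80 to 3.62). miR843, in MIR843 (AT3G48057) on chromosome 3 at 17742147 to 17742167, was the family called lower, with 70 and 158 reads, a ratio of 0.348 (0.259 to 0.464). Family sums can hide single mature sequences, of which these were named after their values were seen. In the uncalled miR169 family (0.908), miR169b-5p was called lower, with 7 and 59 reads, a ratio of 0.0932 (0.0359 to 0.204). In the uncalled miR396 family (1.91), miR396b-5p was called higher, with 220 and 73 reads, a ratio of 2.37 (1.81 to 3.13).

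The other called families were less abundant. miR163, which targets methyltransferases of secondary metabolism, had 46 and 12 reads, a ratio of 3.01 (1.57 to 6.24), with UUGAAGAGGACUUGGAACUUCGAU on chromosome 1 at 24884359 to 24884382 in MIR163 (AT1G66725). miR2111, a phosphate-starvation miRNA, had 40 and 5 reads, a ratio of 6.28 (2.48 to 20.4). It has fewer reads than the naming rule asks for and is named after its values were seen. With all sense reads on the miRNA gene in place of the exact mature sequence, miR163 turned to 0.895, miR846 fell to 1.56 and miR2111 fell to 3.85, still called. With ends within 2 nt counted, miR846 fell to 1.46 (1.29 to 1.65) and its call ended. miR163, miR2111, miR846 and miR857 stayed called under all 4 other scalings, as did miR843, whereas miR394 reached only 1.89 with edgeR's TMM.

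The most abundant families dominated both libraries. miR167, which targets auxin response factors, had 135473 and 106586 reads, a ratio of 0.998 (0.990 to 1.01). miR156/miR157, the juvenile-phase regulator of SPL genes, had 63856 and 41557, a ratio of 1.21 (1.19 to 1.22), and miR172, its counterpart that acts on AP2-like genes, had 28875 and 18870, a ratio of 1.2 (1.18 to 1.22). Both fell below 1 with edgeR's TMM, to 0.902 and 0.899. miR158 had 63396 and 33722 reads, a ratio of 1.48 (1.46 to 1.496), above 1 under each scaling. These 4 families held 89.2% of listed miRNA reads in the library labelled MeJA and 86.1% in the library labelled aos. miR161 had a ratio of 1.36 (1.32 to 1.41), which turned to 0.849 when reads with ends within 2 nt were counted. miR168, which targets AGO1, had 6434 and 9692 reads, a ratio of 0.521 (0.505 to 0.538). miR165/miR166, which targets the leaf polarity HD-ZIP genes, had 4474 and 6872, a ratio of 0.511 (0.492 to 0.531). Both stayed just short of the 2-fold threshold and passed it without structural RNA in the scaling, at 0.453 and 0.444. miR164 had a ratio of 0.947 (0.900 to 0.997). All listed miRNAs together had 326904 and 233179 reads, 14.8% and 13.4% of matched reads, a ratio of 1.10 (1.10 to 1.11) that turned to 0.956 without structural RNA.

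The same miRNAs led both libraries as single sequences. TGAAGCTGCCAGCATGATCTA (miR167, MIR167a, AT3G22886, chromosome 3, 8108090 to 8108110) had 132449 and 104277 reads, and TCCCAAATGTAGACAAAGCA (miR158, MIR158a, AT3G10745, chromosome 3, 3366349 to 3366368) had 63297 and 33665. TGACAGAAGAGAGTGAGCAC (miR156, first of 6 matches in MIR156a on chromosome 2, 10676534 to 10676553) had 40868 and 25445 reads. AGAATCTTGATGATGCTGCAT (miR172, MIR172a) had 27666 and 18271, and TTGACAGAAGATAGAGAGCAC (miR157, MIR157a) had 19740 and 13954.

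miRNAs chosen beforehand for their links to stress and nutrition were sparse. miR319, which targets TCP genes that act on jasmonate synthesis, had 15 and 7 reads, a ratio of 1.68 (0.646 to 4.88), while all sense reads on its genes gave 0.706 (0.650 to 0.767). miR393 had 16 and 20 reads, a ratio of 0.628 (0.305 to 1.28), which was called lower with edgeR's TMM (0.470, 0.228 to 0.954) and turned to 1.19 (1.03 to 1.37) over its genes. For miR398, with 16 and 11 reads, the mature sequence gave 1.14 (0.498 to 2.72), under 1 with edgeR's TMM (0.854), and its genes 1.90 (1.39 to 2.62). For miR395, with 10 and 13 reads (0.604, 0.237 to 1.49), a difference was not detectable at this depth. miR399, the phosphate-starvation signal, had 145 and 65 reads, a ratio of 1.75 (1.30 to 2.39), short of 2-fold, and was called higher over its genes, at 2.49 (1.97 to 3.17).

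By function, 3 lists had 1 family called higher each. In the copper list, miR857 was called and miR397, miR398 and miR408 were not, with a median log2 ratio of 0.55 at percentile 52.1 of random lists. In the nutrient list, miR2111 was called out of 5 measured families (median 0.80, percentile 87.7), and in the development list miR394 was called out of 7 (median 0.70, percentile 94.5). The summed reads of the development list ran the other way, with a ratio of 0.801 (0.780 to 0.822), since miR165/miR166 holds many of them. The small RNA machinery list, with miR162 (1.97), miR168, miR403 (1.58) and miR838 (2.36), had 0 called, a median of 0.82 at percentile 90.04 and a summed ratio of 0.605 (0.588 to 0.623). The auxin list had 0 of 3 called (median -0.24, percentile 14.8), and the triggers of trans-acting siRNAs, miR173 (0.997) and miR390 (0.695), had 0 of 2 called (median -0.27). The list of miRNAs with PPR and immune receptor targets had 0 of 3 called, with a median of 0.39 (percentile 58.1) that reached -0.03 under TMM. Phase change and flowering had 0 of 3 called, with a median of 0.27 (percentile 57.2), -0.15 under TMM, and a mean of -0.02. The remaining families, 13 measured, had 2 called higher and 1 lower, with a median of 0.20 (percentile 29.7) that turned to -0.22 under TMM.

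**Figure D4:**
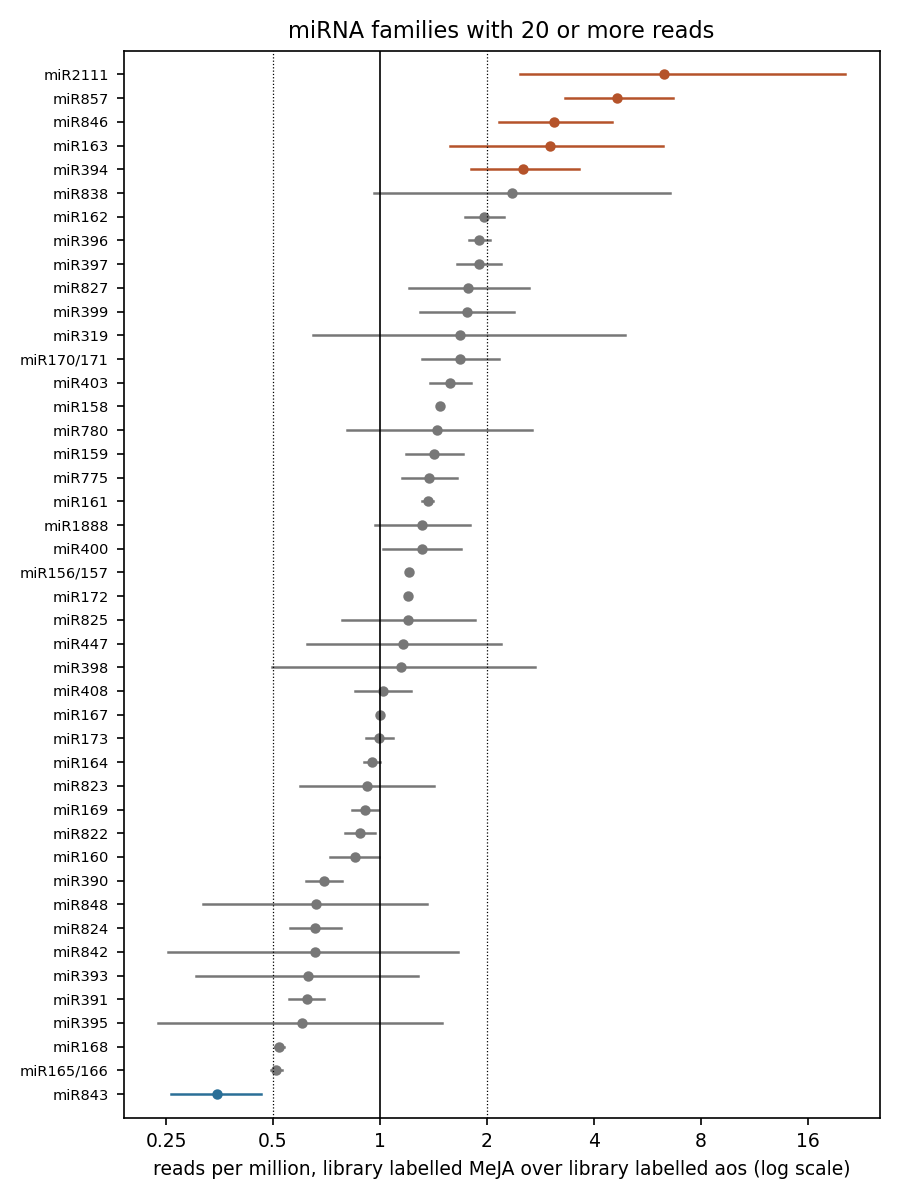
Ratio of RPM, library labelled MeJA over library labelled aos (horizontal axis, log scale), for the 44 miRNA families with 20 or more reads, with 95% counting intervals; orange and blue points are the families called higher and lower, and dotted lines mark 2-fold. miR2111 (6.28), miR857 (4.65), miR846 (3.08), miR163 (3.01) and miR394 (2.53) lie to the right and miR843 (0.348) to the left; miR394 is not called with edgeR's TMM.

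Of the trans-acting siRNA loci, TAS4 was called lower in the library labelled MeJA and TAS3B and TAS3C higher. The 8 TAS loci together had 59554 and 38104 reads of 21 nt, a ratio of 1.23 (1.21 to 1.24) that turned to 0.918 under TMM. TAS4 (AT3G25795, chromosome 3, 9417551 to 9418705), whose siRNAs act on MYB genes of anthocyanin synthesis, had 40 and 93 reads, a ratio of 0.338 (0.227 to 0.494), lower in the library labelled MeJA under all 4 other scalings. TAS3B (AT5G49615) had 176 and 69 reads, a ratio of 2.00 (1.51 to 2.69), and TAS3C (AT5G57735) had 58 and 22, a ratio of 2.07 (1.248 to 3.55). Both calls ended without structural RNA in the scaling, at 1.74 and 1.80. TAS3, which like these makes siRNAs against auxin response factors, had a ratio of 1.14 (1.08 to 1.21). TAS1A (AT2G27400, chromosome 2, 11721539 to 11722468), the largest source, had 20296 and 13579 reads and a ratio of 1.17 (1.15 to 1.2), and TAS1B had 1.11 (1.05 to 1.17). TAS1C and TAS2, neighbours on chromosome 2, had 1.31 (1.28 to 1.34) and 1.27 (1.23 to 1.30). TAS1A, TAS1B, TAS1C, TAS2 and TAS3 fell below 1 under TMM, at 0.878, 0.830, 0.977, 0.947 and 0.855. The directions rest on labels that the jasmonate response and AOS reads ran against.

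siRNAs of 24 nt, which guide DNA methylation, were not called different in most windows of 1000 bp. Of 16406 windows with 20 or more 24-nt reads, 663 were called higher in the library labelled MeJA and 163 lower, so 80.3% of calls were higher. Without structural RNA in the scaling the counts were 314 and 276, with 53.2% higher. With edgeR's TMM 26.0% of calls were higher and with median of ratios 47.6%. Counting error alone, around the ratio of all 24-nt reads, 1.12, would call 320 and 59. A smaller set of windows was nearly private to 1 library, and the jasmonate response and AOS reads ran against the labels of both.

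In the library labelled MeJA, the windows with the largest called ratios were 2 intergenic ones, on chromosome 2 at 14653001 to 14654000 (190 and 0 reads, at least 49.8-fold higher against the floor and 40.1-fold by the interval) and on chromosome 1 at 23076001 to 23077000 (172 and 0, at least 45.0-fold higher and 36.2-fold by the interval). They were followed by chromosome 3 at 10587001 to 10588000, overlapping AT3G28330 (198 and 5, a ratio of 31.1, 13.1 to 96.9). Next was chromosome 5 at 16023001 to 16024000, overlapping AT5G40020 (126 and 4, 24.7, 9.43 to 92.2). In the library labelled aos, the window on chromosome 5 at 6789001 to 6790000, overlapping AT5G20100, had 0 and 112 reads. It was at least 47.5-fold higher there against the floor and 38.0-fold by the interval. The window on chromosome 5 at 15742001 to 15743000, overlapping UDG4 (AT5G39320), had 1 and 100 reads, a ratio of 0.00786 (0.000197 to 0.0448). Windows on chromosome 1 at 12561001 to 12562000, overlapping the noncoding gene AT1G34392 (10 and 177), and on chromosome 5 at 19830001 to 19831000 (10 and 173, intergenic) had ratios of 0.0444 (0.0209 to 0.0836) and 0.0454 (0.0214 to 0.0855). Whether the reads lie within the overlapping genes was not examined.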

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

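All tests in this part were chosen after the result was seen. Reads without a genome match held sequence of T-DNA, the DNA that Agrobacterium vectors insert into plants, in both libraries. The library labelled MeJA-treated wild type had 1499 reads (442 distinct) on a segment just inside the left border, against 2 in the library labelled aos. The library labelled aos had 213 reads on the nopaline synthase terminator, against 2, and 23 on the left border itself, against 0. They lie outside the genome-matched comparisons and above the 3 counts that a count of 0 allows. The neomycin phosphotransferase gene had 12 and 10 reads, and the phosphinothricin and sulfonamide resistance genes and the 35S promoter had 0 and 0.

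The left-border-side reads of the library labelled MeJA were 69.9% of 21 to 22 nt and 21.4% of 24 nt, while the terminator reads of the library labelled aos were 72.8% of 24 nt. Carry-over from 1 library or 1 outside source into both would give both segments the same ratio, but their ratios differed 79822-fold (11185 to 569642). The segments were written after the unmatched reads had been looked at, so the size of this difference is no test. The values bear only on 1 source shared by both libraries, and a separate source for each was not tested. Fragments of vector nucleic acid are argued against by length, since 98.8% and 96.6% of these reads were 20 to 24 nt, against 53.7% and 46.1% of rRNA reads. Plants that carried a T-DNA behind both libraries remain a candidate explanation, since the lesser strand held 38.4% of the left-border-side reads and 41.8% of the terminator reads (17.4% of the left border reads), as double-stranded RNA cut into siRNAs would give. A wild type should carry none, which bears on the label of the library labelled MeJA, but the allele of aos is not stated and the reads of the other library stay open.

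The miR158a-3p variant C3T, counted from 1 at the 5′ end, had 3129 reads without a genome match in the library labelled MeJA and 1080 in the library labelled aos, which is 4.94% and 3.21% of the exact reads. It lies outside the perfect-match counts. It also stands above the limit of a count of 0, which is no test for a variant of so abundant a miRNA. Other C to T changes had many reads too, such as C10T of miR167a-5p with 2072 and 1137, 1.56% and 1.09% of its exact reads. No explanation was tested.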

How the results depend on the processing

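Tests with every annotated miRNA, summed list reads, reads of 18 to 24 nt, scaling to nuclear 24-nt reads and the scalings of genes with 21-nt reads were chosen after the result was seen. No paired analysis was possible because each group has 1 library, and no library could be left out. Over 380 alternatives to 64 results, 243 kept the result and 137 did not. Of these 137, 18 reversed the result and the rest moved, weakened or strengthened it. For the shifts below the cause was not tested beyond the alternative's own construction. Against the floor, AOS stayed 2.97-fold to 3.97-fold higher in the library labelled aos (1.83-fold by the main interval), and the jasmonate response list kept a ratio of 0.0157 to 0.0531. The 24-nt to 21-nt ratio of ratios was 1.09 for matched reads, 1.06 without structural RNA, 1.14 for sequences with 2 or more reads and 0.903 for distinct sequences. Distinct sequences also took the nuclear structural classes together to 0.501 (main 0.315), miRNA genes to 0.856 and TAS genes to 0.905. Total miRNA was 1.09 per total of all reads, 0.956 without structural RNA, 0.823 with edgeR's TMM, 0.917 with median of ratios, 1.08 with ends within 2 nt and 1.19 without the most abundant family. All TAS loci were 1.21 per total of all reads, 1.07 without structural RNA, 0.918 with TMM and 1.02 with median of ratios. TMM also reversed miR156/miR157 (0.902), miR172 (0.899), TAS1A (0.878), TAS1B (0.830), TAS2 (0.947) and TAS3 (0.855), and median of ratios TAS1A (0.978) and TAS1B (0.925). miR161 reversed with ends within 2 nt (0.849) and on the miRNA gene (0.866), as did miR163 on the gene (0.895). Families called higher, 5 in the main setting, were 3 at 100 reads, 12 at 1.5-fold, 2 at 4-fold and 8 with every annotated miRNA. Families called lower, 1 in the main setting, were 3 without structural RNA, 6 with TMM, 3 with median of ratios, 5 at 1.5-fold and 0 at 4-fold. Windows called higher and lower, 663 and 163, were 314 and 276 without structural RNA, 161.0 and 458 with TMM, 263 and 290 with median of ratios, 99 and 34 at 100 reads, 84 and 69 at 4-fold, and 352 and 223 with scaling to nuclear 24-nt reads. The photosynthesis median was -0.77 with TMM, and that of the PPR and immune receptor miRNA list was 0.18 without structural RNA, -0.031 with TMM and 0.13 with median of ratios. At 100 reads no gene list kept a member. Depth limits families under 20 reads and single jasmonate genes, most of which had fewer than 10 reads.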

Other observations

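All tests in this part were chosen after the result was seen, while the counts of AOS and the gene lists that they draw on were planned. Among genes with 21-nt reads, several of the most abundant were near equal between the libraries. AT3G06435 (chromosome 3, 1968288 to 1970946) had 2046 and 1685 reads of 21 nt in the libraries labelled MeJA and aos, a ratio of 0.954 (0.894 to 1.02). Genes of the pentatricopeptide repeat cluster on chromosome 1, whose proteins act on organelle RNA, followed, with AT1G63130 at 707 and 598 (0.929, 0.832 to 1.04), AT1G63080 at 618 and 442 (1.10, 0.971 to 1.24) and RPF3 at 400 and 330 (0.952, 0.821 to 1.10). AFB3, an auxin receptor, had 82 and 66 (0.976, 0.697 to 1.37). Of 132 genes with 20 or more such reads, 16 were called higher in the library labelled MeJA and 1 lower. These counts were 12 and 3 without structural RNA in the scaling and 7 and 4 with edgeR's TMM. The called genes include NIA2 (AT1G37130), a nitrate reductase, with 127 and 40 reads (2.49, 1.74 to 3.65) and AGO1 with 30 and 11 (2.14, 1.04 to 4.74), and NIA1, the other nitrate reductase, had 81 and 33 (1.93, 1.27 to 2.98). The call of NIA2 ended with TMM, at 1.86 (1.30 to 2.73), and that of AGO1 ended without structural RNA, at 1.86 (0.906 to 4.11). These genes were picked after their values were seen.

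Some windows of 24-nt siRNAs were present in 1 library and absent from the other. Among 10259 windows with 40 or more 24-nt reads, 3 had reads only in the library labelled MeJA and 8 only in the library labelled aos, while libraries simulated with counting error alone gave 0 and 0. That simulation holds no spread between plants or preparations, so it does not show that these windows differ by more than 2 separate samples would. The first base of 24-nt reads was A in 62.4% and 63.6%, and that of 21-nt reads U in 66.3% and 69.8%. With every annotated miRNA counted, miR780 had 558 and 100 reads, a ratio of 4.38 (3.54 to 5.48), while its listed mature sequence alone had 35 and 19, a ratio of 1.45 (0.805 to 2.68) within counting error, and miR5648 had 44 and 4, a ratio of 8.64 (3.15 to 33.1).

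The jasmonate genes and AOS were higher in the library labelled aos, against its label. In these 2 libraries the response list's reads argue against a rise under the labelled treatment and genotype. The upper bound of the list's ratio was 0.118, far under 1. That bound covers only counting error in 5 and 81 reads, and it belongs to the values that raised the question. Whether the mRNAs themselves rose was not measured. An equal rise in mRNA fragments of every gene in that library does not account for the response list. Among reads shorter than 20 nt or of 25 nt and more, the list's upper bound was 0.0916, under the ratio of 0.297 for all other genes. A rise that differs between genes is not excluded, since the spread of gene lists around 0.297 was not measured. The photosynthesis list, for example, had a ratio of 0.807 (0.578 to 1.13) over these lengths. For AOS and the synthesis genes even an equal rise stays open. Over these lengths AOS had 0 and 4 reads (upper bound 1.19). The synthesis genes had a ratio of 0.107 with an upper bound of 0.357. An exchange of the labels of the 2 libraries stays open and had no test of its own, since the upper bounds of AOS, 0.545, and of the list are the values that raised it. An exchange alone would not account for the T-DNA reads, since the library labelled aos would then be the wild type and held 213 reads of the nopaline synthase terminator and 23 of the T-DNA left border. Other errors of labelling stay open too.

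Structural RNA was 3.23-fold higher in the library labelled aos, and with 1 library per group an effect of genotype or treatment cannot be told apart from a difference between preparations. A size selection that reached longer RNA is argued against as the whole cause, since reads of 18 to 24 nt alone differed 2.60-fold (2.57 to 2.62), though the ratio rose from 2.32 at 21 nt to 10.7 at 30 nt. More breakdown of long RNA in that library stays open. Protein-coding sense reads outside 20 to 24 nt were 3.37-fold (3.25 to 3.50) and plastid protein-coding reads 1.36-fold (1.33 to 1.40) higher there. The rise was not equal for every RNA, as photosynthesis genes over the same lengths had 76 and 74 reads, 1.24-fold (0.888 to 1.73).

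Reads with 1 mismatch to the 6 most abundant miRNAs and no genome match were 6.80% of exact reads in the library labelled MeJA and 5.35% in the library labelled aos. C to T changes made up 59.6% and 47.7% of them, and A to T, the next kind, 10.6% and 14.6%.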
